A study of Mus musculus with 6 samples.

How the data were processed

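RNA of mouse embryos at the 4-cell stage was sequenced in 6 libraries, 3 control and 3 Son siRNA, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, embryos were lysed directly and cDNA was made with Smart-Seq2. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and the GRCm38 genome build were used. The annotation release, read length, filters and counting script are not given in the sources used here.

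The authors deposited 1 table per library with 46072 genes, each an Ensembl identifier and a symbol with a whole-number estimated count, not normalized. Values of 1 to 40 were multiples of 4 for 26.4% to 32.4% of genes, against 25% by chance, so 1 read pair was taken to be worth about 4 units. This is an assumption from the values and it was not stated by the authors. Counts were used as deposited, with 0 blank or unassigned entries. By Ensembl identifier, 45137 of the 46072 genes matched GENCODE vM21, which uses GRCm38 and gave coordinates, gene types, exon numbers, GC content and lengths; 935 did not match.

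Totals were 112010794, 107996833 and 118865650 units in controls 1 to 3 and 104634855, 114437429 and 114892490 units in siRNA libraries 1 to 3. Mitochondrial genes took 15.3%, 9.8% and 16.0% of the control counts and 13.8%, 17.5% and 13.2% of the siRNA counts. A floor of 3 read pairs, 12 units, corresponds to 0.0906 to 0.125 CPM per library. Spearman correlations of gene counts were 0.886 between controls, 0.904 to 0.908 between siRNA libraries and 0.879 to 0.893 across groups, so no library was a copy of another.

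The main test was edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr, TMM scaling, glmQLFit and glmQLFTest of Son siRNA minus control without a block, and Benjamini-Hochberg adjustment with a threshold of 0.05. Scaling factors were 0.858, 1.05 and 0.810 for controls and 1.16, 1.02 and 1.15 for siRNA libraries. CPM values are TMM-scaled and fold changes are log2. Gene lists, 27 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance 1 way, were alternatives. The single-exon comparison used medians per library and an exact two-sided permutation test over 20 assignments.

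Design, gene lists and the rule for named genes were fixed before the data were examined. Named genes were Son; the 8 largest increases and 8 largest decreases among genes past the threshold whose groups did not overlap and whose mean reached 5 CPM in a group, leaving out predicted genes, clone names and pseudogenes; and up to 4 members of each list with the smallest unadjusted p. The lists were the first lineage and pluripotency regulators, maternal oocyte transcripts, 2-cell-stage genes, core spliceosome, SR and hnRNP regulators, speckle proteins, human SON splicing targets, histone methyltransferases, histone demethylases, DNA methylation, p53 and apoptosis, replication, mitosis, ribosome biogenesis, ribosomal proteins, ATF4, heat shock, compaction, mRNA decay, interferon, respiratory chain, mitochondrial mRNAs, proteasome, histones, and markers of cumulus, sperm and blood cells.

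Exonic overlap and shared stretches of 100 bases with other genes were computed for the named genes, because Smart-Seq2 reads carry no strand. The test was checked on simulated counts drawn from the gene means, library sizes and dispersions of the real libraries, with 200 genes at 5 CPM or more changed and 1 list shifted. Of 16653 simulated genes tested for Son siRNA against control, it recovered 77 of 100 genes changed 4-fold and 98 of 100 changed 8-fold, and called 11 unchanged genes among 187 calls, the shifted list and 0 others. Simulated genes were drawn independently, with 1 dispersion per gene for both groups. The check therefore does not cover lists of correlated genes (estimated correlation 0.649 for ribosomal proteins). It also does not cover groups of unequal spread (median SD of log2 CPM 0.424 in controls and 0.216 after siRNA).

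Alternatives planned for counts were DESeq2 size factors, no filter, a filter of 50 units in 3 libraries, the replicate number as a block, DESeq2 1.42.0 (Wald test) and leaving out each library. Alternatives for FPKM or TPM values did not apply, since the files hold counts. Added later were counts divided by 4, upper-quartile and total-count scaling, leaving out mitochondrial, rRNA and pseudogene entries, offsets for GC content and length, limma-voom with a variance for each group, and single-exon genes against matched genes.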

Results

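The series measured RNA of mouse embryos at the 4-cell stage, after siRNA against Son had been microinjected at the zygote stage. Son encodes a large nuclear speckle protein that binds RNA and acts in pre-mRNA splicing, and the title of the series ties it to splicing and histone methylation in early development. There were 3 control and 3 Son siRNA libraries, made with Smart-Seq2, a full-length cDNA protocol that starts from oligo(dT) priming and does not mark the strand. The labels do not say how many embryos entered a library, what the control injection was, or whether libraries came from separate litters, so p-values measure the spread between these libraries only. Total estimated counts per library ranged from 104634855 to 118865650 units. Counting intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

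Son expression was lower in each of the 3 siRNA libraries than in any control. Son (ENSMUSG00000022961, chromosome 16 from 91647506 to 91679221 on GRCm38) had 249, 322 and 332 CPM (counts scaled by library size and TMM factor) in the controls. The siRNA libraries had 41, 28.0 and 25.1 CPM. The means were 301 ± 45.3 CPM in controls and 31.4 ± 8.48 CPM after siRNA (SD, n = 3 each), which left 10.4% of the control level. The log2 fold change was -3.26 (SE 0.272), with an adjusted p of 0.00991 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact two-sided permutation test gave p = 0.1 for n = 3 against 3, the smallest p this design allows. Without siRNA library 1, 2 or 3 the log2 fold change was -3.50, -3.19 or -3.12, and edgeR's adjusted p was 0.0648, 0.0709 or 0.136, no longer past the threshold.

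**Figure D1:**
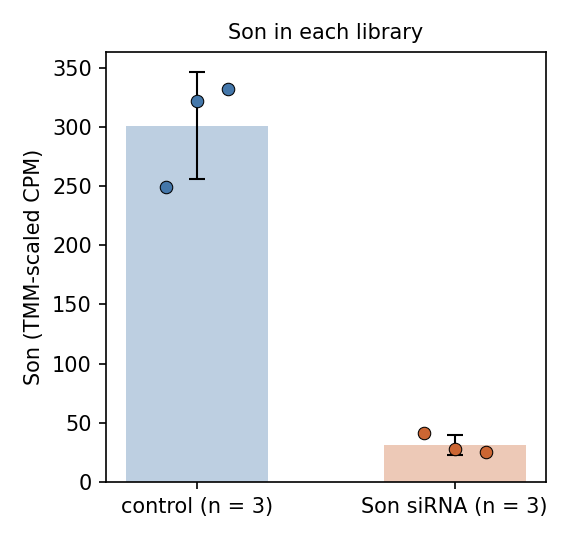
Son in each library, in TMM-scaled CPM. Points are single libraries, bars are group means and error bars are SDs (n = 3); the siRNA libraries lie between 25.1 and 41 and the controls between 249 and 332.

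The main comparison asked which transcripts differed in abundance between embryos with and without Son siRNA. Regulators of the first lineages were among the genes that fell, including Hand1, Klf5 and Dppa2, while Gadd45g, a growth arrest and DNA damage inducible gene, rose. Of 17788 genes tested, 160 were lower and 16 were higher after siRNA at an adjusted p under 0.05 by edgeR's quasi-likelihood test, Son itself among the lower genes. At least 2-fold changes were seen for 159 of the lower and 16 of the higher genes. Protein-coding genes made up 143 of the lower and 15 of the higher genes. Control and siRNA libraries did not overlap for each of the 176 genes; over the tested genes the share without overlap was 23.7%, against 10% by chance.

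Among the genes with the largest increase, Gadd45g (chromosome 13, 51846678 to 51848468) went from 2.89 ± 0.721 to 20.2 ± 1.75 CPM, a log2 fold change of 2.80 (SE 0.335, edgeR adjusted p = 0.0134). Chchd6, a component of the mitochondrial contact site and cristae organizing complex, rose from 0.631 ± 0.234 to 6.39 ± 0.923 CPM (log2 3.34). Zhx1, a zinc finger and homeobox transcriptional repressor, rose from 4.28 ± 0.991 to 20.7 ± 4.57 CPM (log2 2.27), with 11% of its exonic bases shared with a predicted gene. Phc2, a Polycomb repressive complex 1 subunit, rose from 1.97 ± 0.764 to 9.47 ± 2.23 CPM (log2 2.27), and Lgals1, which encodes galectin-1, from 1.17 ± 0.198 to 6.20 ± 1.62 CPM (log2 2.41). Naprt, an enzyme of NAD synthesis, rose by a log2 fold change of 2.98, but 11.8% of its exonic bases overlap Eef1d, which fell (log2 -1.34). Jmjd8 rose by a log2 fold change of 2.30, with 39.3% of its exonic bases shared with Stub1 and a microRNA gene. Gemin4, a subunit of the SMN complex that assembles spliceosomal snRNPs, had the largest fitted increase of these called genes, from 0.327 ± 0.361 to 22.7 ± 4.33 CPM (log2 6.12). Its value is uncertain, since 91.3% of its exonic bases overlap Glod4, Fam57a and Dbil5 and the reads carry no strand.

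Of the genes with the largest decrease, Anpep, which encodes aminopeptidase N (chromosome 7, 79821803 to 79861059), fell from 32.3 ± 6.45 to 1.98 ± 0.514 CPM, a log2 fold change of -4.03 (SE 0.363, edgeR adjusted p = 0.00991). Ckmt1, the mitochondrial creatine kinase, fell from 24.3 ± 7.34 to 1.02 ± 0.460 CPM (log2 -4.57). Aim2, a cytosolic DNA sensor, fell from 14.2 ± 3.47 to 1.37 ± 0.413 CPM (log2 -3.37), and Hes1, a transcriptional repressor downstream of Notch, from 34.0 ± 24.4 to 3.27 ± 2.21 CPM (log2 -3.38). Ren1, which encodes renin, had a log2 fold change of -4.28, Ubxn11 of -3.61 and the carbonyl reductase gene Cbr2 of -3.50. Ly6a, a GPI-anchored surface antigen, was carried by 452 read pairs in controls and 1 in siRNA libraries, if 4 units are 1 read pair. That is a ratio of 547 after scaling (95% counting interval 97.8 to 21700). Control 1 held most of these pairs, and without it Ly6a had 108 pairs in controls and a ratio of 191 (33.5 to 7600), no longer past the threshold (edgeR adjusted p = 0.0895). Without siRNA library 2 Ly6a was at 0 after siRNA, at least 64.8-fold lower against the floor, and not past (adjusted p = 0.112). Without control 1 Gemin4 had a log2 fold change of 7.45 and stayed past (edgeR adjusted p = 0.0277). Hes1 had -2.61 without control 2 and -4.09 without siRNA library 2 (edgeR adjusted p = 0.0572 and 0.0909). Cbr2 had -4.20 without siRNA library 3 (edgeR adjusted p = 0.149). In these fits Hes1 and Cbr2 were no longer past.

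The number of called genes rested on every siRNA library: without siRNA library 1, 2 or 3 edgeR called 0 genes (1786, 2348 and 1733 at an unadjusted p under 0.05), where DESeq2 called 602, 969 and 569, each time including all 176 of the main calls with the same sign. Without control 1, 2 or 3 edgeR called 64, 315 and 87 genes, of which 73.3% were lower without control 2. With all 6 libraries, DESeq2's Wald test called 1228 genes, 823 of them lower (67.0%), and total-count scaling, which shifted the median log2 fold change of all tested genes by 0.29, left 42. Without control 1 DESeq2 called 709 genes lower and 549 higher (56.4% lower), without control 2 1298 and 1218 (51.6%), and without control 3 949 and 817 (53.7%), against 823 and 405 with all libraries. The control libraries also varied more: the median SD of log2 CPM was 0.424 in controls and 0.216 after siRNA over 6079 genes at 10 CPM or more. In a count chosen after the results were seen, genes reaching 3 read pairs after thinning every library to the depth of the smallest numbered 16641 ± 596 in controls and 17874 ± 104 after siRNA (exact two-sided permutation p = 0.1, the smallest possible for n = 3 against 3).

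**Figure D2:**
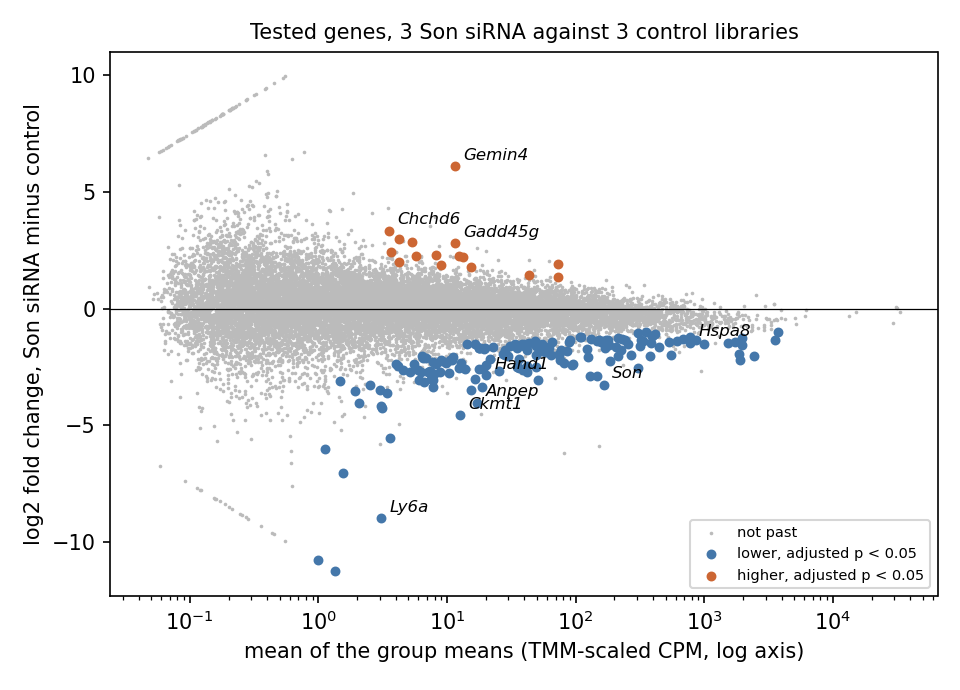
Each point is 1 of the 17788 tested genes, with the mean of both group means in TMM-scaled CPM on a log axis and the fitted log2 fold change, siRNA minus control, on the vertical axis. Blue points are the 160 lower and orange points the 16 higher genes; the diagonal lines of points are genes at 0 in every library of a group, whose fitted fold depends on the prior count.

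Regulators of the first lineages and of pluripotency were lower as a group after Son siRNA. Of 38 tested members, 6 fell and 0 rose by edgeR's adjusted p over all genes, 34 had a fold change below 0, and 14 were lower when adjusted over the list alone. Hand1, a trophoblast transcription factor, fell from 35.5 ± 10.7 to 4.90 ± 1.17 CPM (log2 -2.85, adjusted p = 0.0141). Klf5, needed for trophectoderm and inner cell mass, fell from 63.6 ± 7.58 to 22.8 ± 3.44 CPM (log2 -1.48). Amotl2, an angiomotin of the Hippo pathway, fell from 30.4 ± 14.5 to 5.03 ± 1.53 CPM (log2 -2.60), and Dppa2, an activator of early embryonic genes, from 2536 ± 730 to 928 ± 57.3 CPM (log2 -1.45), although 23.9% of the 100-base stretches of the Dppa2 transcript also occur in other genes. The other called members were Nanog (log2 -2.24) and Fgfr2 (log2 -2.55), named after their values were seen. The list median was -0.94 in log2, with camera's adjusted p = 6.15e-08 at a preset correlation and an adjusted p of 0.312 with an estimated correlation.

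Maternal oocyte transcripts and replication-dependent histones were higher as groups, with 0 single genes past the threshold in either list by edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 12 oocyte transcripts and 6 histone genes, and DESeq2 called 5 and 1 of them higher. Of 50 oocyte transcripts, 40 had a fold change above 0, with a median of 0.67 (camera adjusted p = 0.000114, and an adjusted p of 0.423 with an estimated correlation). Oosp1, an oocyte-secreted protein gene, had 24.4 ± 17.0 CPM in controls and 100 ± 33.8 CPM after siRNA (log2 2.04, edgeR adjusted p = 0.0915; without control 3 log2 2.76 and past, adjusted p = 0.042), and Omt2b had 10.8 ± 3.06 and 33.8 ± 15.9 CPM (log2 1.65, adjusted p = 0.102). Of 36 tested histone genes, 32 had a fold change above 0, with a median of 0.75 (camera adjusted p = 5.41e-05, and an adjusted p of 0.423 with an estimated correlation). Only 8 of the 36 reached 1 CPM in controls, and 1 was at 0 in all controls. Setting that gene at its bound left the median at 0.75. Since cDNA was primed with oligo(dT), these values mainly cover histone transcripts with a poly(A) tail and not total histone mRNA. Hist1h4i had 1.74 ± 0.507 and 5.41 ± 1.45 CPM (log2 1.63, adjusted p = 0.118), and Hist1h2ap had 11.4 ± 2.88 and 21.8 ± 5.88 CPM (log2 0.93, adjusted p = 0.239), with 92.2% of its 100-base stretches shared with other genes.

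The core spliceosome list and the SR and hnRNP list had medians below 0 after Son siRNA with TMM scaling, with few single genes past the threshold. Fold changes were above 0 for 26 and 19 of their members. Of 81 core spliceosome genes, 2 fell, the U2 snRNP subunit gene Sf3b2 (59.4 ± 8.50 to 20.7 ± 3.10 CPM, log2 -1.52) and Bcas2 of the Prp19 complex (190 ± 55.6 to 56.8 ± 18.0 CPM, log2 -1.74), and 5 were lower when adjusted over the list alone. Of 59 SR and hnRNP regulators, Srsf3 fell (564 ± 128 to 202 ± 64.9 CPM, log2 -1.48), and 9 were lower and 1 higher when adjusted over the list alone, the higher one being the neuronal splicing regulator Ptbp2 (log2 1.14). The list medians were -0.24 for the spliceosome (camera adjusted p = 0.00977) and -0.19 for SR and hnRNP genes (camera adjusted p = 0.0301), each with an adjusted p of 0.423 with an estimated correlation. Both calls were lost with total counts, where the medians were 0.06 and 0.10, and the spliceosome call also without control 1 (adjusted p = 0.0674). The SR and hnRNP call was also lost without control 3 or siRNA library 2 (adjusted p = 0.186 or 0.110), with a stricter filter (0.0521) and with counts divided by 4 (0.0522). Of 50 nuclear speckle proteins other than Son, the RNA helicase gene Ddx39b fell (log2 -1.61) and 2 were lower when adjusted over the list alone; the list was not past the threshold (median 0.02, camera adjusted p = 0.753), and its mean and test were signed downward.

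Human splicing targets of SON, a list taken from work on human cells, were lower as a group: 18 of 21 had a fold change below 0, 0 passed edgeR's test over all genes and 3 were lower when adjusted over the list alone. At an unadjusted p under 0.05 there were 6, and DESeq2 called 4 lower. The median was -0.65 (camera adjusted p = 0.000317, and an adjusted p of 0.423 with an estimated correlation). Prdm14, a regulator of pluripotency, had 18.5 ± 18.5 CPM in controls and 1.51 ± 0.356 CPM after siRNA (log2 -3.62, adjusted p = 0.0558; log2 -2.38 without control 1), and the mitotic kinase gene Aurkb had 81.5 ± 8.42 and 38.1 ± 2.74 CPM (log2 -1.09, adjusted p = 0.0609). The list shares 2 members with the lineage list, 5 with the mitosis list and 1 with the proteasome list, and its 13 members in no other list had a median of -0.65.

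Ribosome lists were lower as well with TMM scaling. Of 56 nucleolar and ribosome biogenesis genes, Ftsj3, a pre-rRNA processing factor, fell from 201 ± 34.7 to 48.4 ± 5.77 CPM (log2 -2.06), and Nip7 from 542 ± 64.7 to 242 ± 35.9 CPM (log2 -1.16); the same number, 2, passed when adjusted over the list alone. The list median was -0.33 (camera adjusted p = 0.000622, and an adjusted p of 0.45 with an estimated correlation). With total counts it was -0.046 (camera adjusted p = 0.0437). Of 87 ribosomal protein entries, matched by symbol, Rpl7a (log2 -1.67) and Rpl36 (log2 -2.19) fell, but 53.1% and 55.3% of their 100-base stretches also occur in other genes. The entries include Rps3a2, annotated as a processed pseudogene, with 643, 6.17 and 250 CPM in controls (log2 -5.90, edgeR adjusted p = 0.0749). Of its stretches 78.6% are shared. In that list 5 were lower and 1 higher when adjusted over the list alone. The ribosomal protein median was -0.32 (camera adjusted p = 0.00123, and an adjusted p of 0.752 with an estimated correlation), and without control 1 it was -0.06 (adjusted p = 0.596). With total counts the ribosomal protein median was -0.015 (camera adjusted p = 0.0295). Of 52 mitosis and spindle genes 0 passed edgeR's test over all genes, 12 had an unadjusted p under 0.05, DESeq2 called 9 lower, and 6 were lower when adjusted over the list alone. Among them was the kinetochore motor gene Cenpe (1546 ± 164 and 872 ± 109 CPM, log2 -0.83, adjusted p = 0.0888). The mitosis median was -0.17 (camera adjusted p = 0.0301, and an adjusted p of 0.543 with an estimated correlation). With total counts it was 0.10 (adjusted p = 0.294), and without control 2, control 3 or siRNA library 2 the adjusted p was 0.159, 0.128 or 0.110. A stricter filter and counts divided by 4 ended the mitosis call too (adjusted p = 0.0521 and 0.0522).

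**Figure D3:**
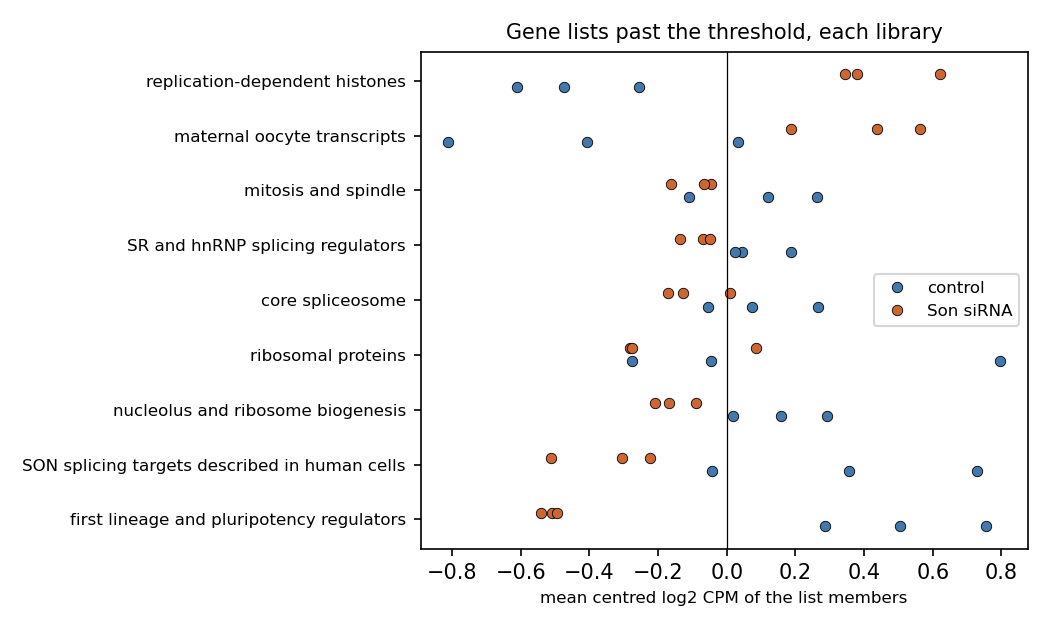
The 9 gene lists past the threshold at camera's preset correlation. Each point is a library, placed at the mean over list members of log2 CPM after centring each gene on its mean over the 6 libraries. For the lineage regulators the siRNA libraries lie between -0.54 and -0.50 and the controls between 0.28 and 0.76. Control and siRNA libraries overlap for the core spliceosome, mitosis and ribosomal protein lists (exact two-sided permutation p = 0.2, 0.3 and 0.5).

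Histone methyltransferase genes and their partners were not past the threshold as a list (51 tested, median -0.07 with the test signed downward and a mean of 0.14, camera adjusted p = 0.844). By edgeR's test over all genes 0 passed, 11 had an unadjusted p under 0.05, DESeq2 called 3 higher and 3 lower, and 3 were higher and 2 lower when adjusted over the list alone. The H3K36 methyltransferase gene Whsc1 had 10.1 ± 2.44 CPM in controls and 31.0 ± 5.16 CPM after siRNA (log2 1.62, adjusted p = 0.0509), and Mtf2, a Polycomb repressive complex 2 partner, had 1790 ± 785 and 641 ± 58.6 CPM (log2 -1.48, adjusted p = 0.0713). Histone demethylases (21 tested, median -0.25, camera adjusted p = 0.173) and the DNA methylation machinery (18 tested, median 0.21, adjusted p = 0.798) were not past either, with 0 members past over all genes or adjusted over the list alone, 1 and 3 at an unadjusted p under 0.05, and 1 lower and 1 higher by DESeq2. Kdm2b had a log2 fold change of -0.92 (adjusted p = 0.108) and Uhrf2 of 0.96 (adjusted p = 0.147).

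Genes that mark the transient activation at the 2-cell stage were not past the threshold as a list (26 tested, median -0.14, camera adjusted p = 0.998 with the test signed upward). Its members Tdpoz4 (56.6 ± 14.7 to 19.5 ± 2.0 CPM, log2 -1.54) and Sp110 (963 ± 257 to 394 ± 16.3 CPM, log2 -1.29) fell, also when adjusted over the list alone. Of their 100-base stretches, 11.6% for Tdpoz4 and 27.7% for Sp110 also occur in other genes. Control libraries differed widely in this list, with mean centred log2 CPM of -0.14, -0.98 and 1.07. Its median ranged from -0.62 without control 2 to 0.59 without control 3 and was 0.27 with total counts, with an adjusted p of 0.162, 0.0735 and 0.926. Genes of DNA replication (48 tested, median -0.03, camera adjusted p = 0.392) and p53 targets with apoptosis genes (34 tested, median 0.32, adjusted p = 0.214) were not past, with 0 members past by edgeR over all genes or adjusted over the list alone and 5 at an unadjusted p under 0.05 in each list; DESeq2 called 1 replication gene lower, and 3 p53 genes higher and 1 lower. Compaction and epithelial genes were not past either (36 tested, median -0.07, adjusted p = 0.149), with 0 members past over all genes, 10 at an unadjusted p under 0.05, 1 higher and 5 lower when adjusted over the list alone and as many by DESeq2. Without control 3 that list was past at the preset correlation (median -0.34, adjusted p = 0.0139) but had an adjusted p of 0.391 with an estimated correlation. Of these, the gap junction gene Gja1 had 914 ± 424 CPM in controls and 278 ± 49.9 CPM after siRNA (log2 -1.72, adjusted p = 0.0554).

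In the heat shock list (27 tested, median -0.19, camera adjusted p = 0.222), the constitutive chaperone gene Hspa8 fell from 1138 ± 35.4 to 413 ± 36.9 CPM (log2 -1.46, edgeR adjusted p = 0.0141), with 31.6% of its 100-base stretches found in other genes. Hspb1 had a log2 fold change of 1.28 (adjusted p = 0.0738), with 42.7% of its stretches shared, and 2 were higher and 2 lower when adjusted over the list alone. In the proteasome list (38 tested, median -0.16, adjusted p = 0.149), the ATPase subunit gene Psmc5 fell from 134 ± 30.5 to 37.5 ± 10 CPM (log2 -1.84). Without siRNA library 2 that list was past at the preset correlation (median -0.32, adjusted p = 0.0422) but had an adjusted p of 0.664 with an estimated correlation. Of its members 1 was higher and 3 lower when adjusted over the list alone. The other lists had 0 members past edgeR's test over all genes. They were mRNA decay (52 tested, median -0.15, camera adjusted p = 0.255), ATF4 and amino acid stress (28 tested, median 0.00194, adjusted p = 0.844), interferon response (16 tested, median -0.44, adjusted p = 0.626), nuclear-encoded respiratory chain (87 tested, median -0.01, adjusted p = 0.844) and mitochondrially encoded mRNAs (13 tested, median -0.06, adjusted p = 0.844). In that order 10, 1, 2, 8 and 0 members had an unadjusted p under 0.05, DESeq2 called 3, 1, 1, 2 and 0 lower and 1 decay gene higher, and 3, 1, 0, 0 and 0 were lower when adjusted over the list alone. Without control 1, whose respiratory chain score of 0.59 stood apart from the -0.33 and -0.43 of the other controls, that list was past and higher at the preset correlation (median 0.47, adjusted p = 0.00257) but had an adjusted p of 0.686 with an estimated correlation. For ATF4 and for the respiratory chain the sign of the mean and of the test differed from that of the median. Psat1, a serine synthesis enzyme gene of the ATF4 list, had a log2 fold change of -0.91 (adjusted p = 0.0554).

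Lists of markers of other cells were not past the threshold. Cumulus and granulosa markers (6 tested, median -0.16, camera adjusted p = 0.396) included Serpine2, at 28.3 ± 4.36 CPM in controls and 35.5 ± 7.30 CPM after siRNA, and Hsd17b1, at 1.10 ± 1.5 CPM in controls and 0 in each siRNA library, at least 11.3-fold lower against the floor (adjusted p = 0.0884; lower when adjusted over the list alone). Without control 1, Hsd17b1 had 0.237 CPM in controls and the bound was 2.43-fold. Sperm markers (4 tested, median 0.36, adjusted p = 0.714) included Odf2, at 20 ± 8.81 and 30.2 ± 4.28 CPM, the only 1 of the 4 to reach 1 CPM in controls. In controls and after siRNA, Prm1 had 0.0768 and 0.141 CPM, Prm2 0.503 and 0.275 CPM, and Gapdhs 0.103 and 0.113 CPM. The sperm list median was 0.99 without control 2, -0.25 without siRNA library 2 and -0.37 with no filter. Blood markers (3 tested, median 0.80, adjusted p = 0.264) included Hba-a2, at 2.10 ± 0.337 and 3.66 ± 0.222 CPM, with 74.5% of its 100-base stretches shared with other genes. The blood list score was higher in each siRNA library than in any control (exact two-sided permutation p = 0.1, the smallest possible for n = 3 against 3). That score is a mean over 3 genes. Hba-a1, the most abundant, was nearly unchanged at 6.90 ± 2.84 and 6.50 ± 0.381 CPM (log2 -0.087). Alas2 had 0.0662 CPM in controls and 0.268 CPM after siRNA (log2 1.99), near the floor.

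Single-exon genes, which need no splicing, were compared with multi-exon genes, since the files hold gene totals and no splice junctions. Relative to 13609 multi-exon protein-coding genes, the median centred log2 CPM of 383 single-exon genes was -0.17 ± 0.17 in controls and 0.20 ± 0.11 after siRNA (SD, n = 3), a difference of 0.37. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1 for n = 3 against 3, the smallest it can give. By edgeR's test, 0 single-exon genes were called higher and 2 lower, against 15 and 141 multi-exon genes. Histone genes were not left out of this comparison. Against 383 multi-exon genes matched on expression and transcript length the difference was 0.29 and the exact permutation p was 0.2, a comparison added after the data were seen.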

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

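Counts divided by 4, upper-quartile and total-count scaling, the fit without mitochondrial, rRNA and pseudogene entries, GC and length offsets, group variances, matched single-exon genes and DESeq2 without single libraries were chosen after the data were seen. All 176 main calls kept their sign in the settings that tested them, and where those settings called genes the share of lower ones ranged from 67.0% to 91.5%. By DESeq2 without single libraries it ranged from 51.6% (without control 2) to 84.2% (without siRNA library 3). The 32 called genes chosen by the naming rule (Son apart) kept their call in 334 comparisons and lost it in 210, with 0 changes of sign. By camera at the preset correlation the 9 lists past the threshold lost the call in 16 comparisons, and 3 calls were gained by other lists. The cause of these shifts was not tested unless it is stated.

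The main counts of differentially expressed genes, 176 (160 lower, 16 higher, 175 with at least 2-fold change), became 100 (91 lower, 9 higher, 100 with 2-fold change) with no filter, which tested 27088 genes. They were 288 (245, 43, 285) with the stricter filter, 1228 (823, 405, 1061) with the DESeq2 Wald test, which left 436 adjusted p-values as NA, and 330 (279, 51, 327) with counts divided by 4. Total counts gave 42 (35, 7, 41), GC and length offsets 499 (415, 84, 442) and group variances 373 (330, 43, 353). Without each library in turn the counts ranged from 0 to 315 (lower genes 0 to 231, higher genes 0 to 84, with 2-fold change 0 to 309), with fewer samples in each fit. Where edgeR called 0 genes, 1733 to 2348 had an unadjusted p under 0.05 and DESeq2 called 569 to 969.

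With the replicate block edgeR called 0 genes (0 lower, 0 higher, 0 with 2-fold change), with 1997 at an unadjusted p under 0.05, and Son expression had a log2 fold change of -3.29 (adjusted p = 0.0617). The block also ended the calls of the SR and hnRNP list (adjusted p = 0.0581) and the mitosis list (adjusted p = 0.0578). The labels do not say whether same-numbered libraries share a litter, day or batch. Deviations of same-numbered libraries correlated at -0.0649, -0.0735 and 0.0502, against -0.0493 to 0.11 for libraries with different numbers. These values gave no sign of pairing but cannot exclude it, so the need for the block stays open. Son expression without each library in turn ranged from -3.50 to -3.12, and its adjusted p over all alternatives from 3.62e-26 to 0.136. Gene lists past the threshold numbered 0 with an estimated inter-gene correlation and 1, the lineage list, with fry, against 9. Without each library they numbered 8 or 9, in part through the gains of the respiratory chain (without control 1), compaction (without control 3) and proteasome (without siRNA library 2) lists. The single-exon difference ranged from 0.33 to 0.44 without each library.

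Genes not called in the main design changed sign in 8 comparisons. With total counts the log2 fold change was 0.039 for mt-Nd1 and 0.246 for Hba-a1. With group variances it was 0.0137 for Hba-a1 and -0.27 for Gapdhs. Without each library in turn, Gapdhs ranged from -0.93 to 0.97, Hba-a1 from -0.35 to 0.25 and Prm2 from -2.93 to 0.34.

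Depth limits low genes: the floor of 12 units is 0.0906 to 0.125 CPM, and 2 called genes were at 0 in all siRNA libraries. Alternatives for FPKM or TPM (pseudocount, quantile normalization, robust limma) were not run, because the files hold counts.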

Other observations

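Tests of the 2-cell-stage explanation and the intervals set around shares, list scores and correlations were chosen after the results were seen, as were the abundant genes, gene families and gene types described first and DESeq2 without single libraries.

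Among the 160 lower genes, 13 had at least 1000 CPM in controls. Spic, an Ets-family transcription factor gene, fell from 3132 ± 773 to 677 ± 74.8 CPM (log2 -2.21, edgeR adjusted p = 0.0122). Trim43a and Trim43b, paralogs of the tripartite motif family, fell from 2964 ± 651 to 769 ± 80.0 CPM (log2 -1.95) and from 3901 to 961 CPM (log2 -2.02). Set, a histone chaperone gene, fell from 5014 ± 648 to 2508 ± 136 CPM, and Pa2g4, a growth regulator that binds ribosomes, from 2940 ± 802 to 991 ± 29.0 CPM (log2 -1.57). The ubiquitin ligase components Fbxo15, Wsb1 and Cul5 fell with log2 fold changes of -1.27, -1.50 and -1.52. Outside this group, Myc fell from 44.2 ± 7.27 to 6.90 ± 1.41 CPM (log2 -2.68) and the pioneer factor gene Foxa1 from 352 ± 57.3 to 102 ± 16.9 CPM (log2 -1.78).

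No enrichment of genes named Zfp, Trim or Slc among lower calls passed the test. Against 11990 tested genes at or above the lowest abundance of a called gene, 5 of 260 Zfp genes were lower where 3.47 would be by chance, 2 of 32 Trim genes where 0.427 would be, and 2 of 163 Slc genes where 2.18 would be (Fisher's exact test, adjusted p = 0.602, 0.203 and 1 over 3 families). Genes typed as sense intronic, snoRNA, scaRNA or miRNA were picked by annotated type, without a check that they lie inside introns. Of these 3993 genes, 186 passed the filter of the main test. Their counts therefore do not measure intronic RNA. They summed to 142.5 ± 18.9 CPM in controls and 144 ± 5.23 CPM after siRNA (exact two-sided permutation p = 1, n = 3 each). In the same TMM-scaled sums protein-coding genes differed by a log2 of -0.30 and processed pseudogenes by -0.56. Neither sum overlapped between groups (exact permutation p = 0.1, n = 3 each, the smallest possible). Protein-coding genes hold most counts of each library, so their sum mainly follows the TMM factors (0.858, 1.05 and 0.810 in controls, 1.16, 1.02 and 1.15 after siRNA). It does not show a fall in protein-coding RNA, and the pseudogene difference includes the same shift.

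More genes were called lower than higher after siRNA. Offsets for GC content and transcript length left 83.2% of calls lower (95% Wilson interval 79.6 to 86.2), which argues against GC content and length as the whole cause in that fit. A variance for each group left 88.5% (84.8 to 91.3), so unequal variances did not account for the imbalance in that fit. These intervals treat called genes as independent and do not measure the spread between libraries. A role of the control libraries stays open, since DESeq2's share fell to between 51.6% and 56.4% when any 1 of them was left out. Scaling stays open: total counts left 42 calls, 83.3% of them lower, with an interval of 69.4 to 91.7 that reaches below the bound of 75% set beforehand. Of the 10 splits of the 6 libraries 1 gave as many calls, the real one with 176 and the highest other with 0, and 10 splits are too few for a share under 0.05. By DESeq2 the share was 67.0%, and 56.4%, 51.6% or 53.7% without control 1, 2 or 3, where higher calls numbered 549, 1218 and 817 against 405 with all libraries, and 79.4%, 78.2% or 84.2% without siRNA library 1, 2 or 3, so the size of the imbalance depends on the test and on which libraries enter; no biological explanation was tested.

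Oocyte transcripts were higher and lineage regulators lower after siRNA. The oocyte median stayed at 0.67 or above under 3 other scalings, with an SE over libraries of 0.268 for its list score. The lineage median stayed below 0, so none of the 3 scalings removed the pattern. They shifted the median log2 fold change of all tested genes by -0.00673, 0.0301 and 0.29, each smaller in size than either list median. A larger shift was not tested. An arrest at the 2-cell stage stays open, since the 2-cell list score differed by 0.0329 with an SE over libraries of 0.642. Extra oocyte or polar body RNA stays open too: 8 of the 10 most abundant oocyte transcripts had a fold change above 0, between the bounds of 6 and 9 set beforehand, with Npm2 (log2 -0.01) and H2afx (log2 -1.27) below.

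Fold change followed gene structure weakly across genes, which are not independent replicates. If splicing load mattered, genes with more exons should be lower, and the Spearman rho with exon number was -0.0572 over 13609 multi-exon genes, with -0.0983 to -0.0137 when each library was left out, which leaves it undecided. A loss focused on GC-rich transcripts with short introns predicted a negative rho with GC content. The rho was 0.0435, which met the bound set beforehand against this explanation. When each library was left out it ranged from -0.0584 (without control 3), beyond that bound, to 0.163 (without control 2). That range was added after the values were seen, and it leaves the explanation undecided. The rho with intron length was 0.112 (0.0604 to 0.153), as high as predicted. Control and siRNA libraries overlapped in the contrast of GC-rich and GC-poor genes (exact permutation p = 0.7, n = 3 each). They also overlapped in the contrasts for intron length, exon number and transcript length (exact permutation p = 0.4, 0.4 and 0.5). The prediction for amplification bias was met. The largest gap between libraries of a group in the contrast of GC-rich and GC-poor genes was 8.49 times the difference between group means. That difference was only 0.139 in log2, so any spread between libraries gives a large ratio. The ratio therefore cannot tell amplification from other differences between libraries. Gene totals therefore may not resolve a splicing effect here, and splice junctions were not analysed here.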
